A study of Homo sapiens with 43 samples.

How the data were processed

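HMC3 cells were exposed to dexamethasone, hydrocortisone, the ethanol vehicle of each dose or medium alone for 3 days, and part of the flasks was followed for 3 further days without hormone. Per the labels' protocols, RNA was extracted with RNeasy kits, libraries were made with a stranded total RNA kit, and they were read as paired ends on a NextSeq 550. The values are whole read counts per Ensembl gene as deposited by the authors in 1 table, with the lanes of a library summed and no normalisation, per its header and values. The submitters' processing notes name FastQC, STAR, featureCounts, Subread and the GRCh38 build; their versions, order and settings are not given in the sources used here. The strand setting of the counting is not stated either, so reads of overlapping and antisense genes cannot be told apart with certainty, and reads of near-identical genes such as the pregnancy-specific glycoprotein, metallothionein, keratin-associated and HSPA1 genes may be split among them. The table held 20052 genes. Symbols were taken from a current name table for 19978 genes and from GENCODE v29 for 70 more, and 4 had neither. The smallest total of a gene over the libraries was 50 and each gene had a count in at least 13 libraries. Positions are those of GENCODE v29 on GRCh38, counted from 1.

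Each library was assigned to its group and replicate number by its title. All 43 columns of counts were used. Depth ran from 7638840 to 24426643 counts per library and, without ribosomal RNA, from 1083530 to 17542261. Ribosomal RNA genes stayed in the library sizes of the planned analysis, and TMM scaling, which trims extreme genes, allowed for their share. In pairs of libraries of the same group the differences exceeded sampling noise (median ratio of the observed to the counting variance 1.45 to 3 over 39 pairs), so no library was counted as a repeat of another.

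The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3; glmQLFit without the legacy option and with robust estimation, then glmQLFTest) with TMM scaling. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 16816 genes. All 43 libraries entered one fit with a coefficient for each of the 17 groups, which left 26 residual degrees of freedom; the 4 day 6 vehicle groups of 1 library are assumed to vary like the others. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05, in each of 19 comparisons. Each hormone dose was compared with its own vehicle on day 3 and with the mean of the 4 vehicle libraries on day 6. Differences between doses or hormones are differences of vehicle-corrected effects, and the washout change is the day 6 effect minus the day 3 effect, each against the mean of all vehicle groups of its day. Fold changes are shown on the log2 scale with standard errors or 95% intervals from the same fit. Levels are CPM of the TMM-scaled library, and marker levels CPM without the ribosomal RNA genes.

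There were 25 gene lists: glucocorticoid receptor targets (39 of 48 tested), metallothioneins (4 of 8), cytokines and NF-kB targets (17 of 32), interferon-stimulated genes (16 of 23), microglia (7 of 24), astrocyte (4 of 8), neuron (3 of 10), oligodendrocyte (3 of 8), endothelial (3 of 8) and fibroblast and pericyte markers (14 of 16), extracellular matrix (26 of 30), the TGF-beta and YAP/SRF response (21 of 21), S-phase (30 of 30) and G2/M genes (30 of 30), cholesterol synthesis (21 of 21), alcohol and aldehyde metabolism (10 of 17), oxidative stress (15 of 16), the unfolded protein and integrated stress responses (20 of 21), heat shock (14 of 14), hypoxia and glycolysis (20 of 20), immediate early genes (23 of 23), the circadian clock (17 of 17), corticosteroid receptors, chaperones and steroid enzymes (13 of 16), p53 targets (15 of 16) and mitochondrially encoded genes (13 of 13). Lists of at least 5 tested members were tested with camera, at a preset correlation of 0.01 and again with an estimated one, and with fry (limma 3.58.1) on log2 CPM with a prior count of 2, adjusted over the lists of a comparison. Camera compares a list with the other genes; fry asks whether a list's genes move one way and makes no comparison with other genes.

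Genes named in the text follow a rule. For hormone against vehicle on day 3 it takes the 6 largest rises and 6 largest falls among genes past the threshold with a mean log2 CPM of at least 1 and no overlap of the libraries, and up to 4 members of each list with the smallest p among those past the threshold. For the other comparisons it takes 5 and 5, and up to 2 per list. FKBP5, TSC22D3, PER1, ZBTB16, KLF9, DUSP1 and NR3C1 are named always; ZBTB16 was not among the genes tested. Some genes that the rule takes are not reported here. The groups, the tests, the gene lists, this rule and most alternatives were set before the data were examined.

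Those alternatives were DESeq2 (1.42.0), RLE size factors in edgeR, no low-count filter, the groups compared fitted alone, the replicate number as a block, the replicate number as a block within treatment (below, the flask block), 1 surrogate variable from sva (3.50.0), other control groups, and each library left out in turn. Chosen after seeing the data were the removal of the ribosomal RNA genes, the removal of the libraries with over 75% or over 90% ribosomal counts, the ribosomal share as a covariate and, for day 6 against day 3 vehicles, the flask block within treatment. Whether replicate numbers pair libraries was judged from the correlation of their deviations from the group means over 5785 genes. Across treatments they did not: 55 of 166 same-numbered pairs exceeded 0.1, with a median of 0.02. Between day 3 and day 6 of a treatment every pair exceeded 0.1 for hydrocortisone 10 µM (0.28 to 0.35) and hydrocortisone 0.01 µM (0.16 to 0.30), whose titles share the flask number, and not for dexamethasone 1 µM (−0.29 to 0.01) or 0.01 µM (−0.06 to 0.27).

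The procedure was tested on simulated counts with the means and library sizes of these samples and 200 genes changed by known folds. Each called changed gene had the right direction in all comparisons. For a 2-fold change on day 3, 69.6% of the genes were called for dexamethasone 1 µM, 72.3% for dexamethasone 0.01 µM, 73.5% for hydrocortisone 10 µM and 70% for hydrocortisone 0.01 µM. For the differences between effects on day 3 it was 68.8% (dexamethasone doses), 63.3% (hydrocortisone doses), 62.5% (hormones at 0.01 µM) and 71.4% (dexamethasone 1 µM against hydrocortisone 10 µM). For the washout changes it was 50% for dexamethasone 1 µM, 52% for dexamethasone 0.01 µM, 63.3% for hydrocortisone 10 µM and 62.5% for hydrocortisone 0.01 µM. Calls on unchanged genes exceeded the share of 0.05 that the threshold sets in most comparisons. The highest numbers were 28 of 149 calls for dexamethasone 0.01 µM on day 3 (7.92% of unchanged genes had an unadjusted p under 0.05), 24 of 153 for hydrocortisone 0.01 µM on day 6 (6.49%) and 19 of 164 for day 6 against day 3 vehicles. There were 13 of 112 for the washout of dexamethasone 0.01 µM, 12 of 110 for that of hydrocortisone 0.01 µM, 10 of 99 for the dexamethasone doses and 14 of 138 for vehicle against medium. The share was below 0.05 for hydrocortisone 0.01 µM on day 3 (2 of 115), dexamethasone 1 µM on day 6 (4 of 119), its washout (3 of 89) and dexamethasone 1 µM against hydrocortisone 10 µM (1 of 87). Up to 100 regroupings of the libraries were refitted for each comparison. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.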

Results

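HMC3 is an immortalised human cell line distributed as microglia, the resident macrophages of the brain. Flasks of HMC3 were kept for 3 days with a glucocorticoid, with its ethanol vehicle or in medium alone, and their total RNA was sequenced. Dexamethasone was given at 1 or 0.01 µM and hydrocortisone (cortisol, the main human stress hormone) at 10 or 0.01 µM, each dose with vehicle flasks of its own. Dexamethasone is a synthetic analogue of hydrocortisone that carries a fluorine, an added methyl group and an extra double bond in ring A. On day 3 each flask was harvested on its own and equal numbers of viable cells were reseeded without hormone, and RNA was taken again on day 6, after a washout of 3 days. The questions set by the design are which genes a stress hormone changed beyond its alcohol vehicle, whether the dose mattered, and what was left after washout. The 43 libraries formed 17 groups: 13 groups of 3 libraries, and 4 day 6 vehicle groups of 1 library each. Day 3 held 12 hormone, 12 vehicle and 3 untreated libraries, and day 6 held 12 hormone and 4 vehicle libraries; no untreated library of day 6 was analysed here. Nothing beyond the labels, which speak of separately harvested flasks, says how independent the replicates were, so p-values measure the spread between these samples.

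Total counts ran from 7638840 to 24426643 per library. Genes from ribosomal RNA repeats on chromosome 21, nearly all of it in 4 genes, took between 9.896% and 94.86% of them, with a median of 29.26%. The share exceeded 75% in 7 libraries that belonged to 7 different groups. The highest were dexamethasone 0.01 µM replicate 3 of day 3 (94.86%, exact 95% binomial interval 94.854 to 94.873%) and replicate 1 of the vehicle of the high hydrocortisone dose of day 3 (91.38%, 91.371 to 91.393%). All other genes together received 1083530 to 17542261 counts. Sequenced reads are not independent molecules, so these intervals cover counting error only. Transcripts encoded by mitochondrial DNA took 8.488 to 16.49% of the non-ribosomal counts. For the hormone comparisons of day 3, the 95% interval of a log2 fold change had a median half-width of 0.24 or 0.25 over 11766 genes.

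**Figure D1:**
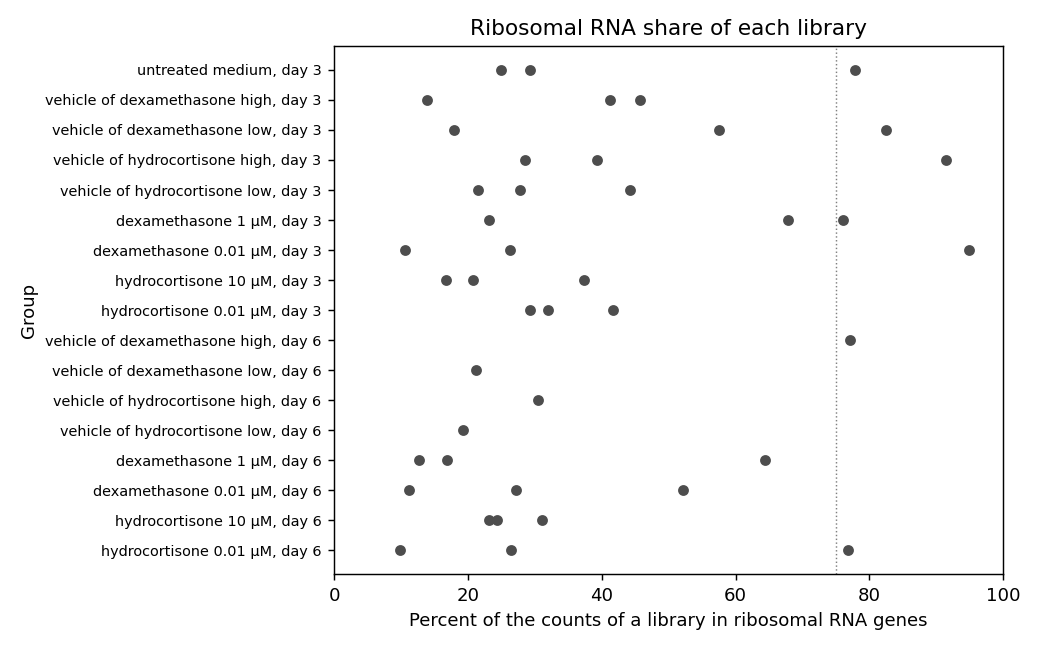
Percent of all counts in ribosomal RNA genes (horizontal axis, 0 to 100%) for each of the 43 libraries. Each point is a library, arranged by group along the vertical axis. The 7 libraries to the right of the dotted line at 75% lie in 7 different groups. The highest value is 94.86% in the dexamethasone 0.01 µM group of day 3.

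The cells carried abundant mesenchymal transcripts and few of microglia. Over all libraries the median levels of COL1A1, the main chain of type I collagen, and of VIM, the intermediate filament vimentin, were 1680 and 1630 CPM (here of the non-ribosomal counts). Those of TAGLN and THY1 were 826 and 280 CPM. Among 14 fibroblast and pericyte markers, 10 had a median above 1 CPM and 7 above 100. Of 24 microglia and macrophage markers, 8 were analysed and 3 had a median above 1 CPM, among them the receptor kinase MERTK (9.04) and OLFML3 (2.05). CSF1R, the receptor that microglia need for survival, and the lipid receptor TREM2 stood at medians of 0.273 and 0.248. Medians above 1 CPM were also found for 4 of 4 analysed astrocyte markers (GJA1, 194), 3 of 5 neuron markers (ENO2, 92.7), 2 of 3 oligodendrocyte markers (CNP, 98.8) and 0 of 6 endothelial markers (VWF, 0.595).

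Dexamethasone at 1 µM changed 3804 of 16816 tested genes on day 3 against its own vehicle (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05, n = 3 and 3). Of these, 1739 rose and 2065 fell, and 442 rose and 314 fell at least 2-fold. TSC22D3 (ENSG00000157514; GRCh38 chromosome X, 107713221 to 107777342, minus strand), which encodes the glucocorticoid-induced leucine zipper protein, rose 15.9-fold, from 3.3 ± 0.973 to 52.6 ± 4.04 CPM of the TMM-scaled library size (mean ± SD, n = 3 each; log2 change 3.99, SE 0.24, adjusted p = 1.9e-12). FKBP5 (ENSG00000096060; chromosome 6, 35573585 to 35728583, minus strand), a co-chaperone that lowers the hormone affinity of the receptor, rose 2.72-fold, from 31.4 ± 4.2 to 85.3 ± 13.5 CPM (adjusted p = 8.15e-11). The clock gene PER1 (ENSG00000179094; chromosome 17, 8140472 to 8156506, minus strand) rose 5.27-fold and the transcription factor KLF9 (ENSG00000119138; chromosome 9, 70384597 to 70414624, minus strand) 3.44-fold.

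Among genes with a mean log2 CPM of at least 1 and no overlap of the libraries, to which rankings by size are limited throughout, the largest rises at 1 µM were those of ADPRHL1 (35.4-fold, ENSG00000153531) and the basement membrane gene NID2 (24.7-fold, ENSG00000087303; chromosome 14, 52004803 to 52069228, minus strand), followed by TSC22D3, CRISPLD2 (10.3-fold), the lipid transporter ABCA8 (9.63-fold) and ENSG00000285417 (8.22-fold). NID2 went from 2.87 ± 0.422 to 71.1 ± 5.38 CPM. The largest falls within these limits were those of MPP4 (38.4-fold), DCDC2 (12.9-fold), HAS2 (11.4-fold), RGS4 (10.7-fold), the activin antagonist FST (10-fold) and PSG6 (9.96-fold), a member of a family of near-identical genes among which reads can be shared. HAS2 (ENSG00000170961; chromosome 8, 121612116 to 121641390, minus strand), a synthase of the matrix polymer hyaluronan, went from 23.8 ± 4.46 to 2.09 ± 0.356 CPM. NR3C1, the glucocorticoid receptor itself, fell by 0.49 on the log2 scale (SE 0.09, adjusted p = 2.62e-05), and DUSP1, a phosphatase of MAP kinases, rose by 1.24 (SE 0.34, adjusted p = 0.00865).

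Of 39 tested targets of the glucocorticoid receptor, 19 rose, 3 fell and 17 did not pass (22 and 3 when adjusted over the list alone), among them NFKBIA, the inhibitor of NF-kB (log2 change 1.53), and the arginine transporter SLC7A2 (1.04). As a set they stood higher than other genes (camera, adjusted p = 6.94e-10, and adjusted p = 0.000279 with an estimated correlation). Of 15 targets of p53, 11 rose and none fell (13 adjusted over the list alone; adjusted p = 9.24e-10, and 0.000758 with an estimated correlation), including CDKN1A, the cell cycle inhibitor p21 (0.96), and MDM2, the ligase that degrades p53 (1.00). Of 16 interferon-stimulated genes, 8 rose and none fell (10 adjusted over the list alone; adjusted p = 9.03e-05, and 0.0134 with an estimated correlation), led by IFIT2 (2.32) and IFIT3 (1.46). The metal-binding metallothioneins MT2A, MT1E and MT1X rose by 0.90, 1.07 and 1.06, with 3 of 4 tested members passing over all genes and over the list alone. Among 17 cytokines and NF-kB targets, 3 rose and 2 fell (5 and 3 adjusted over the list alone; camera adjusted p = 0.536): the chemokine CXCL8 (2.71) and BIRC3 (1.42) were higher, and IL11 (−2.27) and PTX3 (−0.64) lower.

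Matrix and TGF-beta genes moved both ways. Of 26 extracellular matrix genes, 4 rose and 8 fell (6 and 8 adjusted over the list alone), with FBN1, the fibrillin of elastic fibres, at 2.03, the collagen gene COL5A1 at 1.51 and THBS2 at −1.30; the list's median was 0.05, its mean −0.17 and its camera test lower (adjusted p = 0.672). Of 21 genes of the TGF-beta and YAP/SRF response, 6 rose and 5 fell over all genes and over the list alone (camera higher, adjusted p = 0.756; fry lower), with LTBP2 at 1.54 against TGFBI at −2.03 and INHBA at −1.69. Of 14 fibroblast and pericyte markers 7 rose and 2 fell by both adjustments (camera adjusted p = 0.087), with MCAM at 0.67, COL1A2 at −0.62 and VIM at −0.41.

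Metabolic and stress lists shifted by smaller amounts, and none of these set tests passed with an estimated correlation. Of 21 cholesterol synthesis genes, 10 rose and none fell (11 adjusted over the list alone; adjusted p = 0.0035, and adjusted p = 0.3 with an estimated correlation), among them HMGCS1 (0.56). Of 14 heat shock genes, 1 rose, the small chaperone CRYAB (2.01), and 7 fell (2 and 7 adjusted over the list alone), with HSPD1 at −0.66 (adjusted p = 0.0382, and adjusted p = 0.439 with an estimated correlation). Of 20 genes of the unfolded protein and integrated stress responses none rose and 5 fell by both adjustments, TRIB3 (−0.68) and PSAT1 (−0.57) among them (adjusted p = 0.0453, and adjusted p = 0.439 with an estimated correlation). None of 30 S-phase genes rose and 8 fell (9 adjusted over the list alone), CDCA7 by 0.37 on the log2 scale (adjusted p = 0.0287, and adjusted p = 0.439 with an estimated correlation). Of 23 immediate early genes, 8 rose and 1 fell (11 and 3 adjusted over the list alone; adjusted p = 0.044, and adjusted p = 0.816 with an estimated correlation), with JUNB at 1.51 and FOSL1 at −1.24. The mean log2 CPM of this list was 3.40, 3.62 and 3.68 in the hormone libraries and 2.59, 2.53 and 3.42 in those of the vehicle. Against untreated medium the list's direction turned (adjusted p = 0.913), and against all 12 vehicle libraries it did not pass (adjusted p = 0.46). Without 1 library its adjusted p ranged from 0.00104 to 0.221.

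The other lists did not pass camera. Of 15 oxidative stress genes 3 rose and 3 fell (4 and 3 adjusted over the list alone), with FTH1 at 0.64 and TXNRD1 at −0.76. Of 20 hypoxia and glycolysis genes 3 rose and 6 fell (4 and 6), and of 10 alcohol and aldehyde genes 2 rose and 1 fell (2 and 2), with ALDH2 at 0.93. Of 17 clock genes 2 rose and 3 fell (3 and 3; median 0, mean 0.15, camera lower), and of 30 G2/M genes 2 rose and 2 fell (1 and 2; median −0.01, mean 0.01). Of 13 corticosteroid receptors, chaperones and steroid enzymes 2 rose, FKBP5 and the efflux pump ABCB1 (1.45), and 6 fell (3 and 6; median 0.02, mean 0.04, camera lower), with FKBP4 at −0.79. Among cell type markers, 2 of 7 tested microglia genes fell, OLFML3 (−1.17) among them, and none rose (2 fell and 1 rose adjusted over the list alone; median 0.51, mean 0.47, camera lower), the astrocyte transporter SLC1A3 rose by 2.04 while 3 other astrocyte genes fell by both adjustments, 1 of 3 endothelial genes rose by both, and none of 3 neuron, 3 oligodendrocyte (median 0.03, mean −0.31) or 13 mitochondrially encoded genes passed by either. The ribosomal share of these libraries was 23.17 to 76.08% with hormone and 13.91 to 45.65% with vehicle.

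**Figure D2:**
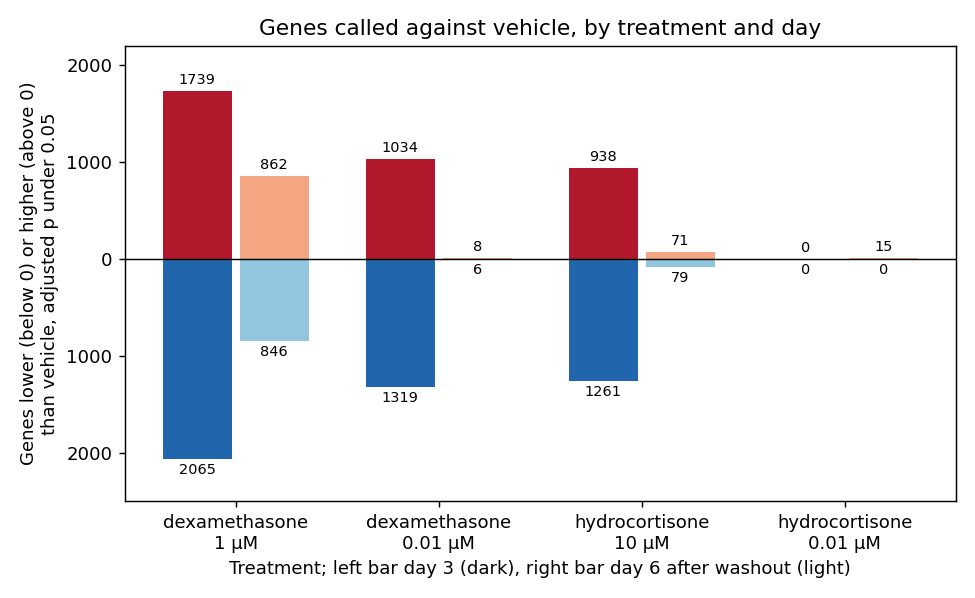
Number of genes higher (above 0) and lower (below 0) than vehicle at an adjusted p below 0.05, by edgeR's quasi-likelihood test. Each hormone dose has a dark bar for day 3 and a light bar for day 6. The bars reach 1739 and 2065 genes for dexamethasone 1 µM on day 3 and are empty for hydrocortisone 0.01 µM on day 3.

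The lower dexamethasone dose, 0.01 µM, changed 2353 genes on day 3, of which 1034 rose and 1319 fell. ADPRHL1 rose 16.2-fold, NID2 10.1-fold, TSC22D3 8.27-fold (3.96 ± 0.457 to 32.9 ± 3.37 CPM, n = 3 each; log2 change 3.05, SE 0.24, adjusted p = 6.06e-10), IP6K3 7.6-fold, CRISPLD2 6.93-fold and ABCA8 6.43-fold. FKBP5 rose 2.34-fold, from 33.4 ± 1.4 to 78.3 ± 2.33 CPM, and PER1 4.14-fold. The largest falls within the limits of level and overlap were those of MPP4 (11.8-fold), DCDC2 (11.5-fold), KRTAP2-3 (8.73-fold, one of a family of similar genes), RGS4 (6.75-fold), the coagulation starter F3 (6.72-fold) and FST (6.32-fold), and HAS2 fell 4.77-fold. NR3C1 fell by 0.46 on the log2 scale (adjusted p = 0.000145), and DUSP1 did not pass (0.72, SE 0.34, adjusted p = 0.169).

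The gene groups at 0.01 µM followed in part those listed for 1 µM. Of the receptor targets 13 rose and 3 fell (16 and 4 adjusted over the list alone; adjusted p = 2.81e-06, and 0.00502 with an estimated correlation), with IRS2 at 1.29. Of the p53 targets 7 rose (10 adjusted over the list alone; adjusted p = 3.92e-05, and 0.0253 with an estimated correlation), and of the interferon genes 4 rose (7 adjusted over the list alone; adjusted p = 0.00135, and 0.0474 with an estimated correlation), RIGI by 1.12 and IFIT2 by 1.17. Cholesterol genes gave 5 rises (6 adjusted over the list alone; adjusted p = 0.00135, and adjusted p = 0.222 with an estimated correlation). TGFBI (−1.85), IL11 (−1.91) and FOSL1 (−1.30) fell, while FBN1 (1.43), COL5A1 (1.08) and the growth factor receptor PDGFRB (0.57) rose. Immediate early genes gave 4 falls and no rise (5 and none adjusted over the list alone), KLF4 among them (−1.58), and the heat shock list 1 rise and 7 falls by both adjustments (camera adjusted p = 0.0786). Dexamethasone replicate 3 (94.86% ribosomal) and vehicle replicate 1 (82.49%) stood apart from the other libraries of this comparison, and without the 7 libraries above 75%, an exclusion chosen after seeing the data, 1522 genes were called. Fitted on its own 6 libraries alone the comparison called 713 genes, and against all 12 vehicle libraries 3633.

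Hydrocortisone at 10 µM changed 2199 genes on day 3, with 938 higher and 1261 lower. ADPRHL1 rose 15.3-fold, TSC22D3 9.59-fold (3.97 ± 0.502 to 38.1 ± 5.39 CPM, n = 3 each; log2 change 3.26, SE 0.24, adjusted p = 1.57e-10), NID2 8.83-fold, ABCA8 7.73-fold, CRISPLD2 7.23-fold and the long non-coding RNA CERNA2 6.78-fold. FKBP5 rose 2.34-fold (34.9 ± 4.75 to 81.6 ± 9.25 CPM), PER1 4.15-fold and KLF9 by 1.56 on the log2 scale. MPP4 fell 12.6-fold, PSG1 8.15-fold, the insulin-like growth factor binding protein IGFBP5 7.61-fold, F3 6.52-fold, KRTAP2-3 5.94-fold, RGS4 5.94-fold and HAS2 5.22-fold. NR3C1 fell by 0.39 (adjusted p = 0.00136) and DUSP1 did not pass (0.66, adjusted p = 0.215).

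With hydrocortisone at 10 µM, 14 receptor targets rose and 2 fell (15 and 4 adjusted over the list alone; adjusted p = 3.2e-08, and 0.00125 with an estimated correlation). All 8 called p53 targets rose (12 adjusted over the list alone; adjusted p = 3.2e-08, and 0.00188 with an estimated correlation), with BTG2 at 1.01 and MDM2 at 0.89, the latter from 105 ± 13.6 to 194 ± 21.9 CPM. Of the matrix genes 5 rose and 11 fell (6 and 11 adjusted over the list alone; adjusted p = 0.0238, adjusted p = 0.492 with an estimated correlation, and the other direction against untreated medium with adjusted p = 0.992), and of the interferon genes 3 rose by both adjustments, IFIT3 by 1.32 (adjusted p = 0.0344, and adjusted p = 0.295 with an estimated correlation). Cholesterol genes gave 2 rises (6 adjusted over the list alone; adjusted p = 0.0115, and adjusted p = 0.355 with an estimated correlation), and the unfolded protein and integrated stress list 4 falls (6 adjusted over the list alone; adjusted p = 0.0158, and adjusted p = 0.295 with an estimated correlation), SLC7A5 (−0.47) among them. Of the G2/M genes 4 rose by both adjustments, CENPF by 0.33 (camera adjusted p = 0.0616). The 13 mitochondrially encoded genes had a median of −0.91 with no member called (adjusted p = 0.00868, and adjusted p = 0.572 with an estimated correlation). The vehicle's replicate 1 held 91.38% ribosomal counts. Without hydrocortisone replicate 4 the comparison called 1396 genes, and against all 12 vehicle libraries 4066.

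Hydrocortisone at 0.01 µM left no gene past the threshold on day 3. TSC22D3 stood at 3.89 ± 0.316 CPM against 3.61 ± 0.43 in its vehicle (log2 change 0.11, 95% interval −0.39 to 0.61), FKBP5 at 32 ± 5.18 against 34.7 ± 1.66 (−0.11, −0.38 to 0.15), PER1 at 0.05 (−0.39 to 0.48) and KLF9 at 0.11 (−0.23 to 0.44). edgeR's quasi-likelihood test called 0 genes, DESeq2 called 1, and 398 of 16816 genes had an unadjusted p under 0.05, with a smallest adjusted p of 0.192. The 95% interval of the change lay within 1 log2 unit of 0 for 98.9% of 11766 genes. No member of any list passed over all genes, and 1 alcohol and aldehyde gene passed when adjusted over the list alone; the p53 list stood higher by camera (adjusted p = 0.0293, and adjusted p = 0.591 with an estimated correlation). Against all 12 vehicle libraries 3 genes were called.

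**Figure D3:**
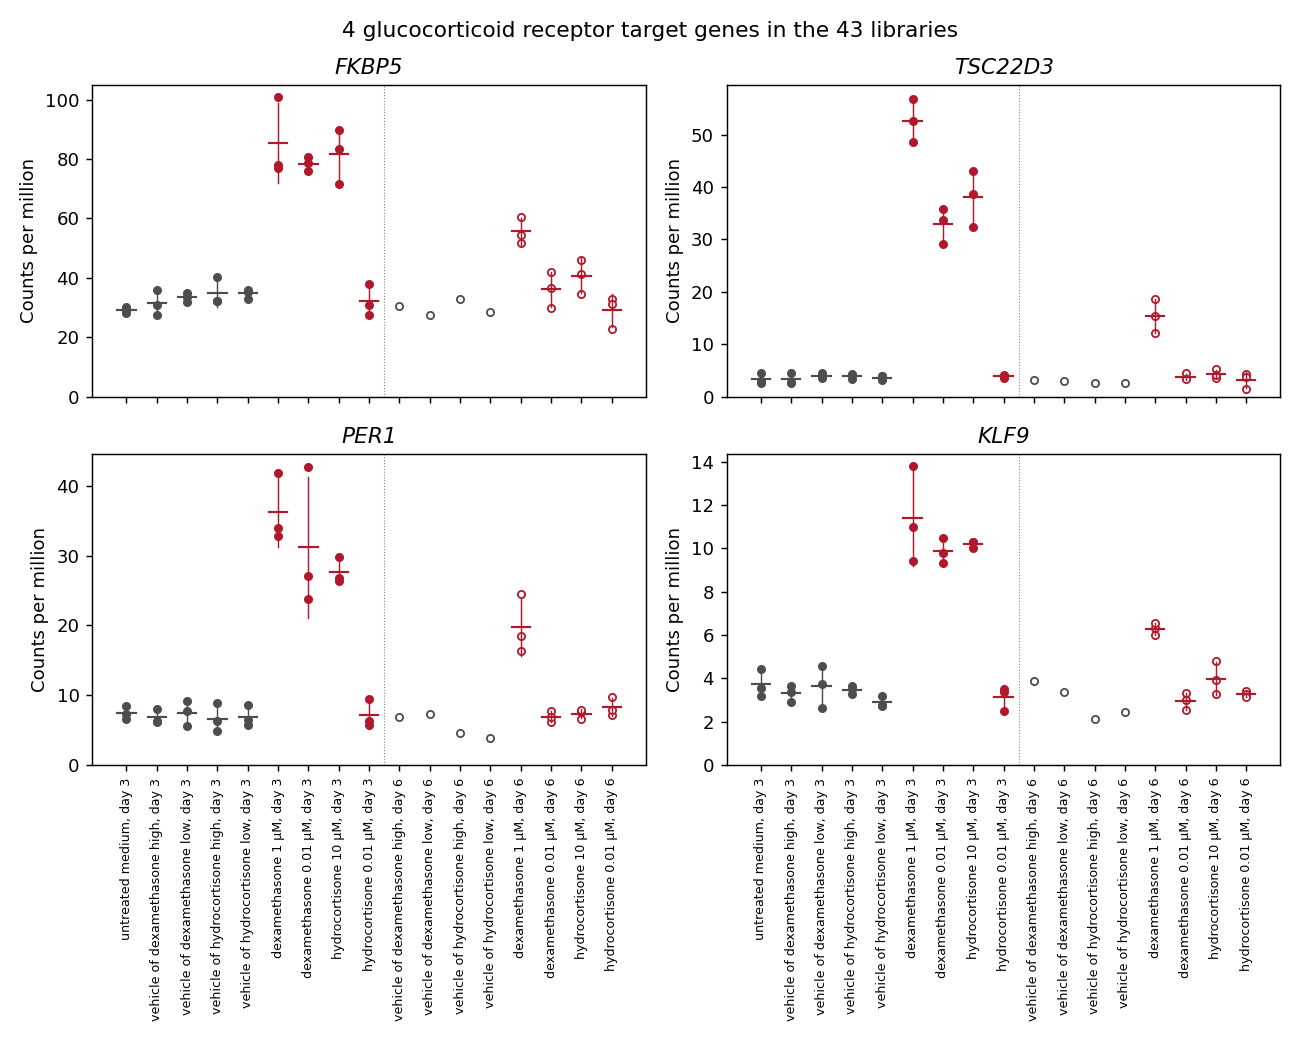
Levels in CPM (vertical axis) of glucocorticoid-responsive genes, one point per library with a bar at the group mean. On day 3 TSC22D3 lies near 3 to 4 CPM in vehicle, medium and hydrocortisone 0.01 µM and at means of 32.9 to 52.6 CPM in the other hormone groups.

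The active treatments shared more of their called genes than independent lists would. Dexamethasone at 1 and 0.01 µM shared 747 risen and 1055 fallen genes, where independent lists of these sizes would share 107 and 162. Dexamethasone at 1 µM and hydrocortisone at 10 µM shared 651 and 932 (97 and 155 for independent lists), and dexamethasone at 0.01 µM and hydrocortisone at 10 µM 486 and 726 (57.7 and 98.9). No gene was called in opposite directions in any of these pairs, which have no control library in common. Across genes, which are not independent replicates, the log2 changes correlated at Pearson's 0.61, 0.58 and 0.50. Over the 1802 genes called at both dexamethasone doses the median size of the log2 change was 0.59 at 1 µM and 0.50 at 0.01 µM, with 72.8% of genes larger at 1 µM.

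The ethanol vehicles were set against untreated medium to see what alcohol alone did. No gene passed edgeR's quasi-likelihood test in 12 vehicle against 3 medium libraries; DESeq2 called 0, 903 genes had an unadjusted p under 0.05 and the smallest adjusted p was 0.553. FKBP5 was at 29.1 ± 0.896 CPM in medium (log2 difference of vehicle 0.21, SE 0.10, adjusted p = 0.936) and TSC22D3 at 3.36 ± 1.05 CPM (0.13, adjusted p = 0.996). Camera placed immediate early genes lower in vehicle (median −0.35, adjusted p = 0.000166, and adjusted p = 0.676 with an estimated correlation), and, with the adjusted p again first at the preset and then at an estimated correlation, matrix genes (0.000396, then 0.416; 1 member risen over the list alone), fibroblast markers (0.00686, then 0.416) and hypoxia genes (0.0328, then 0.502) higher. Medium replicate 3 held 77.9% ribosomal counts, and without medium replicate 1 the test called 3 genes.

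Between the vehicles of the high and the low hormone doses 1 gene passed, IGFBP3, a binding protein of insulin-like growth factors, named here after its values were seen (log2 difference 0.36, SE 0.05, adjusted p = 0.00089; n = 6 and 6). At an unadjusted p under 0.05 there were 1132 genes. Immediate early genes were lower by camera with the high-dose vehicles (adjusted p = 7.91e-05, and adjusted p = 0.62 with an estimated correlation) and p53 targets higher (adjusted p = 0.0011, and adjusted p = 0.19 with an estimated correlation), with 1 p53 gene risen over the list alone. DESeq2 called 3 genes higher and 1 lower, a replicate block gave 3 and leaving out replicate 3 of the vehicle of the high hydrocortisone dose gave 12.

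Whether the dexamethasone dose mattered was tested as the difference between the vehicle-corrected effects of 1 and 0.01 µM, and 8 genes passed. HAS2 (log2 difference −1.25, SE 0.19, adjusted p = 0.000473) and the matrix gene THBS2 (−0.52, adjusted p = 0.0352) were lower at 1 µM. Outside the rule for named genes, and chosen after their values were seen, NID2 (1.29), the adhesion molecule ALCAM (0.52) and the lipin LPIN3 (0.82) were higher, and the protease PAPPA (−0.95), the sialyltransferase ST6GAL2 (−0.79) and MAP3K7CL (−0.56) lower. TSC22D3 differed by 0.94 (95% interval 0.24 to 1.65, adjusted p = 0.615), KLF9 by 0.33 (−0.15 to 0.81), PER1 by 0.35 (−0.27 to 0.96) and FKBP5 by 0.21 (−0.16 to 0.58). As sets the receptor targets (median 0.22, none called; adjusted p = 0.000319, and 0.0301 with an estimated correlation) and the p53 targets (3 risen over the list alone; adjusted p = 1.38e-05, and 0.0301 with an estimated correlation) were higher at 1 µM. Immediate early genes were higher too (adjusted p = 1.38e-05, and adjusted p = 0.634 with an estimated correlation), 2 metallothioneins were higher over the list alone and 2 matrix genes lower (2 higher and 2 lower over the list alone). The count rested on single libraries: it was 4 without dexamethasone 1 µM replicate 2 or without replicate 1 or 2 of its vehicle, 5 without replicate 4 of that vehicle, dexamethasone 0.01 µM replicate 2 or replicate 3 of the latter's vehicle, and 18 without dexamethasone 0.01 µM replicate 3, the library with 94.86% ribosomal counts. DESeq2 gave 14 genes, and the hormone libraries compared directly 65.

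For hydrocortisone, 688 genes differed between 10 and 0.01 µM after correction for vehicle, 291 higher and 397 lower at 10 µM. TSC22D3 differed by 3.15 (95% interval 2.45 to 3.86), CRISPLD2 by 2.64, PER1 by 2.00 (1.39 to 2.62), KLF9 by 1.45 (0.97 to 1.93) and FKBP5 by 1.34 (0.97 to 1.71). HAS2 (−2.27), IL11 (−1.77), TGFBI (−1.44) and the AP-1 member FOSL1 (−1.20) were lower at 10 µM. Among the receptor targets, 11 were higher and 1 lower (12 and 2 adjusted over the list alone; adjusted p = 1.96e-08 at the preset, then 0.000829 at an estimated correlation), of the p53 targets 2 higher (7 over the list alone; adjusted p = 2.09e-05, then 0.02), MDM2 by 0.84, and of the interferon genes 3 higher (4 over the list alone; adjusted p = 0.0218, then 0.221). The limit of overlap pooled each dose here with the other dose's vehicle, so it also required the vehicles to differ, and TSC22D3 failed it. The 13 called genes that met it included ACCS (1.27), KLF11 (1.11) and ATP5F1D (−0.74). NR3C1 did not pass (−0.29, adjusted p = 0.207). Compared directly, without correction for vehicle, the hormone libraries gave 2493 genes.

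The hormones met at a matched dose only at 0.01 µM, where 838 genes differed after correction for vehicle, 348 higher and 490 lower with dexamethasone. TSC22D3 was higher by 2.94 on the log2 scale (95% interval 2.23 to 3.65, adjusted p = 1.45e-06), CRISPLD2 by 2.58, PER1 by 2.00 (1.39 to 2.62), KLF9 by 1.34 (0.86 to 1.82) and FKBP5 by 1.34 (0.97 to 1.71). COL5A1 (0.94), ABCB1 (1.17) and PDGFRB (0.62) were higher with dexamethasone, and HAS2 (−2.14), IL11 (−1.67), TGFBI (−1.62), FOSL1 (−1.19), FTL (−0.65) and PRDX1 (−0.63) lower. Of the receptor targets 10 were higher and 2 lower (11 and 2 adjusted over the list alone; adjusted p = 1.22e-06 at the preset, then 0.00364 at an estimated correlation). Of the interferon genes 3 were higher (4 over the list alone; adjusted p = 0.000692, then 0.0417), of the p53 targets 1 by both adjustments (adjusted p = 0.00673, then 0.179) and of the cholesterol genes 1 (2 over the list alone; adjusted p = 0.00673, then 0.372). The limit of overlap again required the vehicles to differ, and 28 of the 838 genes met it. ALDH1L2 (1.44), ARHGAP31 (1.26), SIRPA (0.71), the pseudogene ETF1P2 (−1.50) and UNKL (−1.15) were among them. NR3C1 (−0.37, adjusted p = 0.0783) and DUSP1 (0.71, adjusted p = 0.501) did not pass. Fitted on their own groups alone the libraries gave 431 genes, and compared directly 2409.

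At the higher doses the hormones differed in concentration, 1 µM of dexamethasone against 10 µM of hydrocortisone, and 5 genes differed. COL5A1 was higher (0.65, SE 0.11, adjusted p = 0.00357) and HAS2 lower (−1.12, SE 0.19, adjusted p = 0.00285) with dexamethasone. The others, chosen after their values were seen, were NID2 (1.48), the kinase DMPK (1.22) and the lysosomal protease CTSC (−0.59). TSC22D3 differed by 0.73 (95% interval 0.03 to 1.44, adjusted p = 0.487), FKBP5 by 0.22 (−0.15 to 0.59), PER1 by 0.35 (−0.27 to 0.96), KLF9 by 0.23 (−0.25 to 0.70) and NR3C1 by −0.11 (−0.36 to 0.14). With the adjusted p given first at the preset and then at an estimated correlation, camera ranked higher with dexamethasone the receptor targets (0.0121, then 0.218), the interferon genes (0.00571, then 0.218; 3 over the list alone), the p53 targets (0.0239, then 0.381), the TGF-beta list (0.0308, then 0.53), the immediate early genes (0.000184, then 0.56) and the mitochondrially encoded genes (2.56e-05, then 0.539), and lower the G2/M genes (0.0251, then 0.56). The count was 2 without dexamethasone replicate 4 (76.08% ribosomal), 3 without replicate 2 of its vehicle and 8 without replicate 3 of the vehicle of hydrocortisone. DESeq2 called 6 genes higher and 1 lower, 1 gene was called without the libraries above 75%, and 23 when the hormone libraries were compared directly. In that direct comparison the p53 (adjusted p = 0.274) and G2/M lists (adjusted p = 0.648) had the other direction.

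After 3 days without hormone, 1708 genes differed between flasks that had received dexamethasone at 1 µM and the 4 day 6 vehicle libraries, 862 higher and 846 lower (n = 3 and 4). On day 3, 620 and 695 of these had been called in the same direction. TSC22D3 stood at 15.4 ± 3.23 CPM against 2.55 to 3.08 CPM in the vehicle libraries (log2 change 2.47, SE 0.23, adjusted p = 5.67e-09), FKBP5 at 55.6 ± 4.55 against 27.5 to 32.9 CPM (0.90, adjusted p = 9.98e-07) and NID2 at 19.1 ± 2.19 against 2.7 to 4.86 CPM (2.57, adjusted p = 7.44e-19). ADPRHL1 (4.11), CRISPLD2 (2.96) and TLR4, the receptor for bacterial lipopolysaccharide (2.29; 12.5 ± 0.95 against 2.37 to 2.9 CPM), were among the largest rises within the limits of level and overlap. DCDC2 (−3.38), MPP4 (−2.92), IGFBP5 (−2.87), FST (−2.51) and PSG1 (−2.21) were the largest falls. PER1 (1.86), KLF9 (1.12) and NR3C1 (−0.30, adjusted p = 0.0104) passed on both days, and DUSP1 did not pass (0.66, adjusted p = 0.207).

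Among the receptor targets, 15 were higher and 3 lower on day 6 (17 and 3 adjusted over the list alone; adjusted p = 4.26e-09, and 0.000627 with an estimated correlation), of the p53 targets 9 higher (10 over the list alone; adjusted p = 2.81e-09, and 0.000856 with an estimated correlation) and of the interferon genes 6 higher (10 over the list alone; adjusted p = 0.00011, and 0.0146 with an estimated correlation). CDKN1A was at 0.84, MDM2 at 0.62, IFIT3 at 1.28 and SLC7A2 at 1.16. Cytokines gave 6 rises and 1 fall (7 and 1 over the list alone; camera adjusted p = 0.0641), with BIRC3 at 1.08 and IL11 at −1.10. Matrix genes gave 4 rises and 9 falls (6 and 10), with FBN1 at 1.56 and COL5A1 at 0.88, and the TGF-beta list 5 rises and 5 falls (7 and 8; median −0.01, mean 0.07), with INHBA at −1.26. Of the unfolded protein and integrated stress list 4 fell by both adjustments (adjusted p = 0.00119, and adjusted p = 0.0918 with an estimated correlation), PSAT1 (−0.74) and TRIB3 (−0.70) among them. The comparison called 1064 genes without dexamethasone 1 µM replicate 2, and 1134 with the vehicles of dexamethasone alone. Of the vehicle libraries the one for the high dexamethasone dose held 77.12% ribosomal counts.

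Fewer genes passed on day 6 for the other treatments. For dexamethasone at 0.01 µM 14 genes differed, 8 higher and 6 lower: TXNIP (1.46), an inhibitor of thioredoxin, ADPRHL1 (1.42), DHRS2 (1.02), CRISPLD2 (0.83) and NPTX1 (0.61) were higher, and IGFBP5 (−1.12), ABI3BP (−0.82), PSG1 (−0.81), ALDH6A1 (−0.50) and INHBA (−0.49) lower. FKBP5 (0.28, adjusted p = 0.616), TSC22D3 (0.43, adjusted p = 0.719) and PER1 (0.35, adjusted p = 0.737) did not pass. Of the receptor targets 2 were higher (5 over the list alone; adjusted p = 0.00547, and adjusted p = 0.132 with an estimated correlation), and, with the adjusted p in the same order, camera also ranked higher the p53 targets (0.000683, then 0.118; 2 over the list alone), cytokines (0.00547, then 0.209), hypoxia genes (0.00547, then 0.209; 3 over the list alone), heat shock genes (0.0182, then 0.439) and G2/M genes (0.0196, then 0.526). The count was 0 without dexamethasone 0.01 µM replicate 2, 1 without the vehicle library of the high dexamethasone dose, 9 without that of the low one and 23 without that of the high hydrocortisone dose. Its own groups alone gave 4 genes, 3 of them among the 14.

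For hydrocortisone at 10 µM 150 genes differed on day 6, 71 higher and 79 lower. ADPRHL1 (2.15), TXNIP (1.49), CRISPLD2 (1.41), CHST2 (1.31) and HTRA1 (1.11) led the rises within the limits of level and overlap and IGFBP5 (−1.26), FST (−1.18), PSG1 (−1.11), the sodium channel SCN9A (−1.11) and ABI3BP (−1.01) the falls. FKBP5 (0.45, adjusted p = 0.0597) and TSC22D3 (0.62, adjusted p = 0.243) did not pass. Among the receptor targets, 3 were higher (6 over the list alone; adjusted p = 5.75e-05, and 0.0172 with an estimated correlation), and of the matrix genes 3 were higher and 1 lower (3 and 8), COL5A1 at 0.39 and VCAN at −0.58. The near-identical heat shock genes HSPA1A (0.46) and HSPA1B (0.53) were higher, both adjustments giving 2 (adjusted p = 0.00153, and adjusted p = 0.241 with an estimated correlation), as were 2 hypoxia genes by both (adjusted p = 0.00221, and adjusted p = 0.215 with an estimated correlation). DESeq2 called 83 higher and 155 lower. The count was 34 without hydrocortisone 10 µM replicate 3, 67 without its replicate 4, 77 without the vehicle library of the high dexamethasone dose and 60 with the vehicles of hydrocortisone alone. Its own groups alone gave 306 genes, 128 of them among the 150.

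Hydrocortisone at 0.01 µM, which had no called gene on day 3, had 15 higher and none lower on day 6. HTRA1 (1.37), SPRY2 (1.08, adjusted p = 0.00935), ARRDC3 (1.06), the non-coding ENSG00000228327 (1.04) and SFT2D3 (1.02) led them within the limits of level and overlap. SPRY2, which restrains growth factor signalling, stood at 6.9 ± 1.15 CPM against 2.55 to 4.65 CPM in the vehicle libraries. Of the immediate early genes 2 were higher, and 18 when adjusted over the list alone, with a median of 0.93 (adjusted p = 1.13e-17, and adjusted p = 0.0892 with an estimated correlation). With the adjusted p in the same order, camera also ranked higher the receptor targets (0.000406, then 0.0558; 5 over the list alone), the p53 targets (0.0178, then 0.258; 3 over the list alone), the unfolded protein list (0.0178, then 0.258; 2 over the list alone) and the matrix genes (0.039, then 0.567). PER1 (0.61, adjusted p = 0.261) and DUSP1 (0.75, adjusted p = 0.416) did not pass. Fitted on its own groups alone the comparison called 6 genes higher and 2 lower, none of them among the 15. In counts simulated for this comparison 24 of 153 calls fell on unchanged genes. DESeq2 called 22 higher and 3 lower, 11 of them among the 15. The count was 1 without hydrocortisone replicate 3, 8 without its replicate 2 (76.77% ribosomal), 4 without the vehicle library of the high hydrocortisone dose, 85 without that of the low dexamethasone dose, and 237 with the vehicles of hydrocortisone alone.

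**Figure D4:**
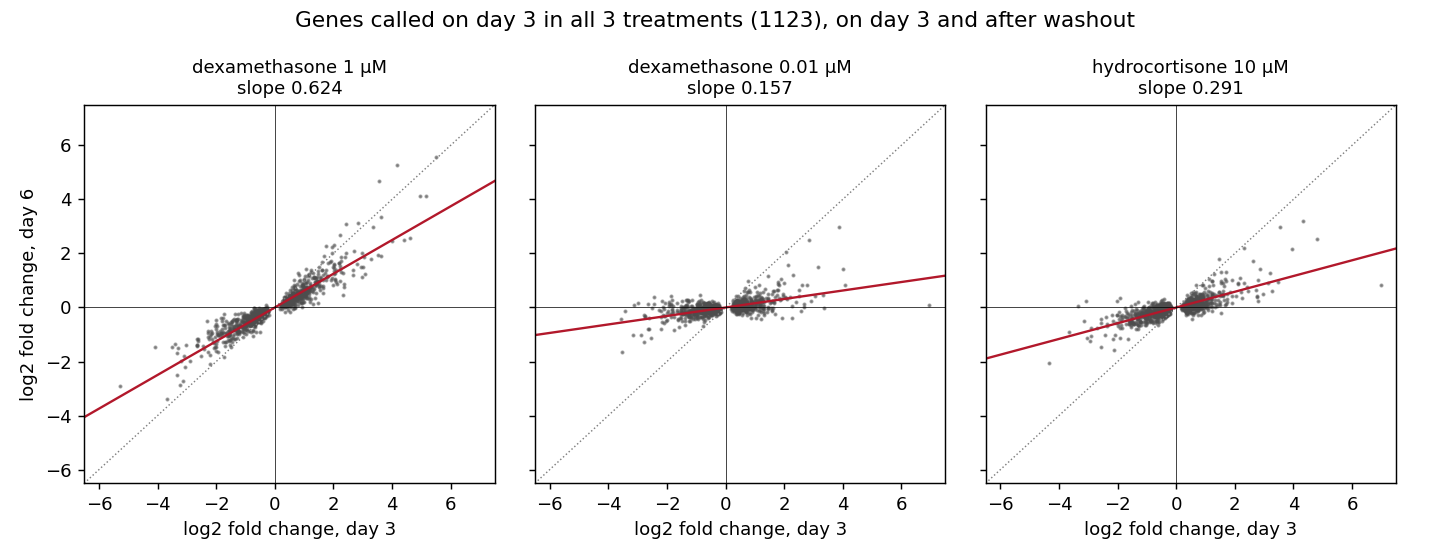
Log2 fold change on day 6 (vertical axis) against that on day 3 (horizontal axis) for the 1123 genes called with all of dexamethasone 1 µM, dexamethasone 0.01 µM and hydrocortisone 10 µM on day 3, one panel per treatment and one point per gene, with a line through 0. The slopes of the lines are 0.624, 0.157 and 0.291 in this order.

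Set side by side over the 1123 genes called with the 3 active treatments on day 3, the day 6 changes were 0.624 of the day 3 changes for dexamethasone 1 µM, 0.157 for dexamethasone 0.01 µM and 0.291 for hydrocortisone 10 µM (slopes through 0). Leaving out any 1 library moved these slopes within 0.601 to 0.65, 0.146 to 0.167 and 0.271 to 0.302. Dexamethasone 1 µM had 620 genes higher and 695 lower on both days (89.1 and 104 for independent lists) and 2 in opposite directions. Hydrocortisone 10 µM had 44 and 64 (3.96 and 5.92) with 2 opposite, and dexamethasone 0.01 µM 4 and 4 (0.492 and 0.471). Of the genes called on day 3, 94.1%, 71.9% and 63.6% kept their sign on day 6 in the order dexamethasone 1 µM, hydrocortisone 10 µM and dexamethasone 0.01 µM.

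The washout change itself was tested as the day 6 effect minus the day 3 effect, each against all vehicle libraries of its day. For dexamethasone 1 µM it passed for 283 genes, 187 higher and 96 lower. HAS2 (2.00), TGFBI (1.33), IL11 (1.33) and FOSL1 (1.07) moved up, and TSC22D3 (−1.36, adjusted p = 0.00964), IRS2 (−0.62), ABCB1 (−0.58) and MT2A (−0.46) down, while FKBP5 (−0.44, adjusted p = 0.183) and PER1 (−0.51, adjusted p = 0.463) did not pass. Of the receptor targets 3 moved down (1 up and 7 down over the list alone; adjusted p = 0.00373 at the preset, then 0.1 at an estimated correlation), of the cholesterol genes none over all genes and 8 down over the list alone (adjusted p = 1.41e-08, then 0.0279), and of the heat shock genes 4 up (6 up and 1 down over the list alone; adjusted p = 0.000927, then 0.185). The p53 targets were lower (adjusted p = 0.0119, then 0.185). Without dexamethasone replicate 4 of day 6 the count was 159.

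For dexamethasone 0.01 µM the washout change passed for 1101 genes, 674 higher and 427 lower. TSC22D3 (−2.72), CRISPLD2 (−1.81), PER1 (−1.80), KLF9 (−1.54), IRS2 (−1.21), FKBP5 (−0.94) and DNAJC6 (−0.97) moved down, and HAS2 (2.24), IL11 (2.23), TGFBI (1.96), FOSL1 (1.46) and NR3C1 (0.43) up. The receptor targets gave 3 up and 10 down (4 and 11 over the list alone; adjusted p = 0.000179 at the preset, then 0.0383 at an estimated correlation), the cholesterol genes 6 down (8 over the list alone; adjusted p = 3.75e-05, then 0.103) and the heat shock genes 6 up and 1 down (adjusted p = 0.0171, then 0.361). Hypoxia genes moved up, 4 of them called (adjusted p = 0.0255, then 0.361), and interferon genes were lower with none called (adjusted p = 0.0199, then 0.21).

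For hydrocortisone 10 µM it passed for 1172 genes, 725 higher and 447 lower. TSC22D3 (−2.74), CRISPLD2 (−1.66), PER1 (−1.55), IFIT2 (−1.53), KLF9 (−1.15), ABCB1 (−1.09), MDM2 (−0.98) and FKBP5 (−0.83) moved down, and HAS2 (2.20), IL11 (1.66), TGFBI (1.42) and FOSL1 (1.23) up. All 8 called p53 targets moved down (11 over the list alone; adjusted p = 2.22e-11 at the preset, then 0.000448 at an estimated correlation), as did 8 receptor targets with 1 up (8 and 2 over the list alone; adjusted p = 1.91e-05, then 0.00721) and 3 interferon genes by both adjustments (adjusted p = 0.00246, then 0.0712). Heat shock genes gave 6 up and 1 down (7 and 1; adjusted p = 0.000144, then 0.0999), cholesterol genes 2 down (3; adjusted p = 0.00596, then 0.307) and S-phase genes 2 up (adjusted p = 0.0119, then 0.415). Deviations of same-numbered libraries of the 2 days correlated for this treatment, which does not establish pairing. Blocking on the number gave 1404 genes, 800 higher and 604 lower, with 936 of the 1172 among them. Without replicate 4 of day 3 the count was 709.

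For hydrocortisone 0.01 µM 1 gene passed, the protease inhibitor SERPINE2 (log2 difference 0.74, SE 0.13, adjusted p = 0.022), named after its values were seen, with 901 genes at an unadjusted p under 0.05. With the adjusted p at the preset and then at an estimated correlation, camera ranked higher the immediate early genes (2.22e-06, then 0.347; 2 over the list alone), the matrix genes (0.00106, then 0.268), the unfolded protein list (0.0056, then 0.241), the receptor targets (0.0185, then 0.241), the TGF-beta list (0.025, then 0.337) and the clock genes (0.0412, then 0.241). Same-numbered flasks of the 2 days deviated together here too, and the block on them gave 0 genes. The count was 0 without replicate 2 or 4 of day 3, without replicate 2 or 3 of day 6 or without the day 6 vehicle library of the high dexamethasone dose. It was 2 without replicate 4 of the day 3 vehicle of the high dexamethasone dose, replicate 2 of that of the high hydrocortisone dose or any of the other 3 day 6 vehicle libraries, 3 without replicate 2 of the day 3 vehicle of the low dexamethasone dose, and 4 without replicate 4 of day 6.

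The vehicle flasks of day 6 differed from those of day 3 in 85 genes, 37 higher and 48 lower (n = 4 and 12). ARRDC3 (−0.91), the clock repressor BHLHE40 (−0.89), the TGF-beta inhibitor SMAD7 (−0.85), TGM2 (−0.80) and ID3 (−0.79) fell, and DCDC2 (1.69), GCNT4 (0.53), MAMDC2 (0.45), DNAJC6 (0.34) and SLC39A10 (0.33) rose, ranked within the limits of level and overlap; 9 of the 48 genes that fell did so at least 2-fold. TGFBI (−0.56), COL5A1 (−0.44) and MT2A (−0.39) fell as well. Immediate early genes were lower with none called over all genes and 17 over the list alone (adjusted p = 1.25e-13, and adjusted p = 0.0804 with an estimated correlation). Cholesterol genes gave 1 fall (5 over the list alone; adjusted p = 9.44e-08, and 0.0333 with an estimated correlation), and in the same order hypoxia genes 1 (4; 1.6e-05, then 0.0333), p53 targets 1 (2; 9.05e-05, then 0.0333), receptor targets 2 (3, and 1 rise; 0.00327, then 0.0782), matrix genes 2 (6, and 1 rise; 0.000613, then 0.175) and the TGF-beta list 3 (6; 0.00454, then 0.175). With the adjusted p in that order, S-phase (0.00149, then 0.175), mitochondrially encoded (5.36e-07, then 0.22), cytokine (0.0472, then 0.247), unfolded protein (0.039, then 0.221), heat shock (0.0472, then 0.303) and receptor and chaperone genes (0.0472, then 0.239) ranked lower too, and 2 metallothioneins fell (4 over the list alone). The count was 17 without the vehicle library of the high dexamethasone dose (77.12% ribosomal) and 56 without that of the low hydrocortisone dose. With flasks of the same number on both days taken as blocks, a fit chosen after seeing the data, 161 genes were called, 99 higher and 62 lower. Of these, 47 were among the 85.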

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

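Chosen after the result was seen were the tests of why hydrocortisone 0.01 µM called no gene on day 3 and the test of a common fading rate after washout. So were the splits of the libraries for hormone against vehicle on day 3 and for the dose and hormone differences, and the fit of day 6 against day 3 vehicles with the flask as a block. The other tests were set down before.

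The effects of the treatments were compared between doses, hormones and days in tests of the difference itself (edgeR's quasi-likelihood test). Between dexamethasone 1 and 0.01 µM 8 genes differed, between hydrocortisone 10 and 0.01 µM 688, between dexamethasone and hydrocortisone at 0.01 µM 838, and between dexamethasone 1 µM and hydrocortisone 10 µM 5. The day 6 effect differed from the day 3 effect in 283 genes for dexamethasone 1 µM, 1101 for dexamethasone 0.01 µM and 1172 for hydrocortisone 10 µM. For hydrocortisone 0.01 µM it differed in 1, where the block of flask within treatment gave 0.

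The pattern to follow up first is that hydrocortisone at 0.01 µM called 0 genes on day 3 (edgeR; 398 genes had an unadjusted p under 0.05, and DESeq2 called 1) while dexamethasone at the same dose called 2353. If too few libraries or too little depth had hidden a response of similar size, those 2353 genes would still lean the same way on average. Their median log2 change, signed by the dexamethasone effect, was 0.35 at hydrocortisone 10 µM and 0.03 at 0.01 µM, a ratio of 0.08 (0 to 0.14 without any 1 library), with 61.3% of signs shared, which argues against that explanation for a response near that of 10 µM. Ribosomal RNA as what hid it is argued against by its share, at most 44.16% in the 6 libraries compared, while the comparison of dexamethasone 0.01 µM called its 2353 genes with a library at 94.86%. A weaker action of hydrocortisone at this dose stays open as a hypothesis, and so does a loss of hormone during culture, which was not tested.

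The second is that the day 3 changes of dexamethasone 1 µM were kept to day 6 in larger part than those of the other treatments, over the 1123 genes called with all 3. If changed transcripts faded at a common rate whatever the treatment, the slopes of day 6 on day 3 would be alike. The lowest slope for dexamethasone 1 µM without 1 library was 0.601 and the highest of the other treatments, also without 1 library, 0.302, which argues against a common rate. A dependence on 1 of the single day 6 vehicle libraries is argued against by a slope of at least 0.613 without any of them, and ribosomal RNA as the whole source because without the libraries above 75% the gap to the next treatment was 0.334 against 0.333, a ratio of 1. A hormone that persists longer at 1 µM may be the source, a hypothesis that no measurement here tests.

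The third is that immediate early genes stood higher on day 6 after hydrocortisone 0.01 µM. Low values in the 4 day 6 vehicles as a set are argued against. Their median log2 difference from the 9 other hormone libraries was −0.06 (camera adjusted p = 0.622, and 0.862 with an estimated correlation). The hydrocortisone vehicles of day 6 had list means of 2.2 and 2.44 log2 CPM, and the dexamethasone vehicles 2.76 and 2.97. Low hydrocortisone vehicles stay open as a part. The treatment stays open, as the list was also higher than in those 9 libraries (median 0.76, adjusted p = 4.56e-11, and adjusted p = 0.174 with an estimated correlation). Handling of single flasks stays open too: the mean of the list spread between libraries of a group with an SD of 0.34 on the log2 scale, against a median of 0.07 for 10000 random lists, percentile 100. The treatment, the handling of its flasks and low hydrocortisone vehicles may all contribute, and these libraries do not separate them.

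For hormone against its vehicle on day 3, 6 libraries form 10 splits, too few for a share under 0.05. As many genes as in the real split were called in 1 of 10 for dexamethasone 1 µM (3804; highest other 0), 1 of 10 for dexamethasone 0.01 µM (2353; highest other 231) and 1 of 10 for hydrocortisone 10 µM (2199; highest other 1), and for hydrocortisone 0.01 µM all 10 of 10 gave 0, as many as the real split. The split with 231 genes exchanged dexamethasone replicate 3, the library with 94.86% ribosomal counts, for vehicle replicate 2. For vehicle against medium, with 0 genes in the real split (edgeR and DESeq2; 903 with an unadjusted p under 0.05), all 100 of 100 drawn splits necessarily gave as many. They therefore say nothing on chance; the highest other gave 53. Chance is not excluded for high against low vehicle (16 of 100; 1 gene; highest other 101). The split with 101 genes, many times the real count of 1, points to a structure among these libraries that the groups do not follow.

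On day 6 the 7 libraries form 35 splits. Only the real split, 1 of 35, called as many genes for dexamethasone 1 µM (1708) and dexamethasone 0.01 µM (14, highest other 11). The same held for hydrocortisone 10 µM (150, highest other 44). This lowest possible share does not exclude chance, and the counts rested on single libraries. Without its replicate 2 dexamethasone 0.01 µM gave 0 genes (edgeR, 835 with an unadjusted p under 0.05) and dexamethasone 1 µM 1064. Hydrocortisone 10 µM gave 34 without its replicate 3. The highest other for dexamethasone 1 µM, 1041 genes, kept its 3 libraries together beside 1 vehicle. For hydrocortisone 0.01 µM the splits do not argue against chance, since 5 of 35 gave at least 15 genes. The highest other gave 126, which points to a structure of these samples.

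For day 6 against day 3 vehicles 3 of 100 drawn splits gave as many as the 85 genes called, and the highest other gave 112. These splits do not keep the flasks together from which the day 6 cells were reseeded, so their share does not settle chance for this comparison. The split with 112 exchanged the day 3 and day 6 libraries of the same flask number in the high and the low hydrocortisone vehicle. With the flask as a block within treatment 161 genes were called, 47 of them among the 85; with 1 day 6 library per vehicle it was not checked whether these flasks pair. The count was 17 without the day 6 dexamethasone high vehicle and 56 without the hydrocortisone low one.

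The dose, hormone and washout differences have 20 splits of the treated libraries with the vehicles left in place, too few for a share under 0.05. As many genes were called in 2 of 20 for the dexamethasone doses (8; highest other 14), 2 of 20 for the hydrocortisone doses (688; highest other 2061), 2 of 20 for the hormones at 0.01 µM (838; highest other 1360), 3 of 20 for the higher doses (5; highest other 85), 2 of 20 for the washout of dexamethasone 1 µM (283; highest other 1130), 2 of 20 for dexamethasone 0.01 µM (1101; highest other 2540), 2 of 20 for hydrocortisone 10 µM (1172; highest other 2358) and 11 of 20 for hydrocortisone 0.01 µM (1; highest other 144). Except for the dexamethasone doses, the highest other exchanged all treated libraries of the pair, so that the vehicle difference added to the hormone difference in place of being subtracted. These exchanges keep the hormone effect, and their higher counts point to a structure of the samples in which vehicle groups differ the same way as their hormone groups. These splits replaced a first draw of 100 that also regrouped the vehicles, a change made after the first draw for the dose and hormone differences was seen. There as many genes were called in 12, 12, 10 and 9 splits for the 4 dose and hormone differences and in 13, 12, 9 and 21 for the 4 washout changes. Of these, 7, 12, 10 and 8, and 13, 12, 9 and 4, the real split included, kept the treated libraries of each group together and with them the hormone effect, so the shares do not measure chance. Splits that mixed treated libraries reached the real count for the dexamethasone doses, the higher doses and the washout of hydrocortisone 0.01 µM, and for no other of the 8 comparisons.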

How the results depend on the processing

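The removal of ribosomal genes, the removal of libraries above 75% or 90% ribosomal counts the ribosomal share as a covariate and, for day 6 against day 3 vehicles, the flask block were chosen after seeing the data; the other alternatives were planned, and for the values below the cause was not tested. Over genes named in the text, the alternatives set beforehand, other than leaving out a library, kept direction and side of the threshold in 5569 cases, weakened the call in 231, strengthened it in 12 and reversed 1; those chosen later gave 3051, 171 and 2, and leaving out 1 library 7970, 525 and 5. In a further 225, 131 and 405 cases a change that passed in neither setting had the other sign. For gene lists the alternatives set beforehand gave 1160 cases with direction and side kept, 58 that lost the call, 16 that gained it, 49 of the other sign without a call and 4 reversed. The reversals were PHGDH for hydrocortisone 10 µM on day 3 with untreated medium as control (0.06, adjusted p = 0.685), the immediate early list for dexamethasone 1 µM on day 3 with that control (camera adjusted p = 0.913), the matrix list for hydrocortisone 10 µM with that control (0.992), and the G2/M (0.648) and p53 lists (0.274) for dexamethasone 1 µM against hydrocortisone 10 µM when the hormone libraries were compared directly.

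Counts that moved by over 1.5 times were these. With DESeq2, hydrocortisone 0.01 µM on day 3 had 1 gene, high against low vehicle 4, the dexamethasone doses 14, and on day 6 hydrocortisone 10 µM 238 and hydrocortisone 0.01 µM 25. Fitted on their own groups, dexamethasone 0.01 µM on day 3 had 713, the dexamethasone doses 1, the hormones at 0.01 µM 431, on day 6 dexamethasone 0.01 µM 4, hydrocortisone 10 µM 306 and hydrocortisone 0.01 µM 8 (none of the 15), and the washout of hydrocortisone 0.01 µM 0; a fit on fewer libraries has fewer degrees of freedom. Without the ribosomal genes the dexamethasone doses gave 4, and on day 6 hydrocortisone 10 µM 251 and 0.01 µM 9. Without the libraries above 75%, dexamethasone 0.01 µM on day 3 gave 1522, the higher doses of the hormones 1, the washout of hydrocortisone 0.01 µM 0 and day 6 against day 3 vehicles 37. Without those above 90%, high against low vehicle gave 4, the dexamethasone doses 36, on day 6 dexamethasone 0.01 µM 23, hydrocortisone 10 µM 265 and 0.01 µM 30, and the washout of dexamethasone 1 µM 433. With 1 surrogate variable, hydrocortisone 10 and 0.01 µM on day 6 gave 230 and 23. Against all 12 vehicles of day 3, dexamethasone 0.01 µM gave 3633, hydrocortisone 10 µM 4066 and 0.01 µM 3. Compared directly, the dexamethasone doses gave 65, the hydrocortisone doses 2493, the hormones at 0.01 µM 2409 and at the higher doses 23. With the day 6 vehicles of the same hormone alone, dexamethasone 1 and 0.01 µM gave 1134 and 60, and hydrocortisone 10 and 0.01 µM 60 and 237.

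A replicate block on the number alone, which did not pair the libraries, gave 3 genes for high against low vehicle and 8 for hydrocortisone 0.01 µM on day 6, and moved no other count by over 1.5 times. The block of flask within treatment gave 0 for the washout of hydrocortisone 0.01 µM and 1404 for hydrocortisone 10 µM. For dexamethasone 1 and 0.01 µM it gave 265 and 1220. The check did not settle whether these flasks pair. Day 6 against day 3 vehicles, not checked for pairing, gave 161.

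Leaving out 1 library gave the following ranges, with libraries that moved a count by over 1.5 times. On day 3 dexamethasone 1 µM gave 2779 to 3390, dexamethasone 0.01 µM 1643 to 2351, hydrocortisone 10 µM 1396 (without its replicate 4) to 2310, and hydrocortisone 0.01 µM 0 to 0. Vehicle against medium gave 0 to 3 (without medium replicate 1) and high against low vehicle 1 to 12 (without replicate 3 of the hydrocortisone high vehicle). The dexamethasone doses gave 4 (without replicate 2 of 1 µM, or replicate 1 or 2 of its vehicle) to 18 (without replicate 3 of 0.01 µM). The hydrocortisone doses gave 485 to 816 and the hormones at 0.01 µM 564 to 948. The higher doses gave 2 (without dexamethasone replicate 4) to 8 (without hydrocortisone vehicle replicate 3).

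On day 6 dexamethasone 1 µM gave 1064 (without its replicate 2) to 1725. Dexamethasone 0.01 µM gave 0 (edgeR, without its replicate 2, where 835 genes had an unadjusted p under 0.05) to 23 (without the hydrocortisone high vehicle). Hydrocortisone 10 µM gave 34 (without its replicate 3) to 174. Hydrocortisone 0.01 µM gave 1 (without its replicate 3) to 85 (without the dexamethasone low vehicle). The washout changes gave 159 (without day 6 replicate 4) to 311 for dexamethasone 1 µM, 775 to 1207 for dexamethasone 0.01 µM and 709 (without day 3 replicate 4) to 1277 for hydrocortisone 10 µM. For hydrocortisone 0.01 µM they gave 0 (without day 3 replicate 2 or 4, day 6 replicate 2 or 3, or the day 6 dexamethasone high vehicle) to 4 (without day 6 replicate 4). Day 6 against day 3 vehicles gave 17 (without the day 6 dexamethasone high vehicle) to 114. Of simulated 1.5-fold differences between effects on day 3, 14.6 to 31.2% were called. The real ones had 95% intervals with a median half-width of 0.35 log2 units. Depth, the spread between flasks beyond counting error (1.45 to 3 times the counting variance) and the 3 libraries per group set this width together and were not separated.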

Other observations

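The families below were picked after their values were seen, and the direction of each median given held under each other scaling tried (RLE and DESeq2 size factors, ribosomal RNA genes removed) except where a range says otherwise. No enrichment test was run on them. Histone, integrin, semaphorin, protocadherin, tubulin and keratin families were also examined and are not described. All 10 tested pregnancy-specific glycoprotein genes, secreted relatives of carcinoembryonic antigen, fell with dexamethasone 1 µM (median log2 change −2.36), dexamethasone 0.01 µM (−2.00) and hydrocortisone 10 µM (−2.20) on day 3, and none with hydrocortisone 0.01 µM (−0.18). On day 6 all 10 were still lower after dexamethasone 1 µM (−1.46), 3 after hydrocortisone 10 µM (−0.75) and 1 after dexamethasone 0.01 µM (−0.32). These genes are near-identical copies, so the counts of single members are uncertain and the family is safer than any member. Of 21 keratin 18 pseudogenes, which can share reads with their parent gene, 11, 9 and 7 fell in the same 3 comparisons (medians −1.43, −1.26 and −1.26). Of 8 keratin 8 pseudogenes none was called in any of these 3 by edgeR (medians −0.58, −0.01 and 0.17; the second ranged from −0.19 to 0 under the other scalings).

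Of 78 cytosolic ribosomal protein genes, 63 fell with dexamethasone 1 µM on day 3 (median −0.41), 51 with dexamethasone 0.01 µM (−0.31) and 26 with hydrocortisone 10 µM (−0.21, with 1 higher), and on day 6 after dexamethasone 1 µM 20 were lower and 1 higher (−0.15). Of 17 aminoacyl-tRNA synthetase genes, the enzymes that charge transfer RNAs, 13, 6 and 9 fell on day 3 (−0.31, −0.12 and −0.21) and 11 were lower on day 6 after dexamethasone 1 µM (−0.22). Of 26 collagen genes, 9 rose and 2 fell on day 3 with dexamethasone 1 µM (median 0.23), 10 and 2 with dexamethasone 0.01 µM (0.26) and 7 and 2 with hydrocortisone 10 µM (0.05). On day 6, 7 were higher and 4 lower after dexamethasone 1 µM (0.10), 1 and 1 after hydrocortisone 10 µM (0.14), and 0 and 0 by edgeR after dexamethasone 0.01 µM (0.06). Of 194 solute carriers, 40 rose and 19 fell on day 3 with dexamethasone 1 µM, 24 and 11 with dexamethasone 0.01 µM and 24 and 17 with hydrocortisone 10 µM. On day 6, 23 were higher and 8 lower after dexamethasone 1 µM, 0 and 0 by edgeR after dexamethasone 0.01 µM, and 4 and 4 after hydrocortisone 10 µM.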
